A study of Drosophila melanogaster with 2 samples.

How the data were processed

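Chromatin immunoprecipitation sequencing (ChIP-seq) had been done on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying, males and females together, from a transgenic line that makes the E(spl)m3-HLH protein with a green fluorescent protein (GFP) at its C terminus. Per the labels, an antibody against GFP was used for the precipitation, although the antibody field of the labels names the E(spl)m3-HLH protein itself, and chromatin was sheared by sonication to fragments of 200 to 800 bp. The series held 1 group of 2 biological replicates, numbered 2 and 3 in the labels, each a separate embryo sample with 1 technical replicate. Other replicates and the control library were not analysed here.

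Per the labels and the listings deposited with the files, the authors called peaks separately on each replicate's alignments and on the alignments of both replicates together, each time with a control file, on the genome builds dm6 and dm3. The lists of single replicates and of pooled alignments were described as peaks and background made as input for the irreproducible discovery rate (IDR) procedure, which keeps peaks ranked alike in replicates. A further list per build was the IDR-thresholded result, which is called the thresholded list here. Aligner, peak caller and their versions are not given in the sources used here.

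Each deposited list gave intervals, a signal value per peak, a −log10 q value per peak and the position of the summit. The signal is the enrichment score that the authors' peak caller gave each peak. Its scale is not stated and was set within each list, so signal was used only to rank and describe peaks within a list, and signals of different lists were compared by rank or correlation. The −log10 values of the authors, by the order of columns in this file format, are q values and were not used for any selection. No list gives read counts, so sequencing depth is unknown, and no value here carries a counting error from reads. Confidence intervals of shares are Wilson intervals at 95% and cover only the sampling of peaks or genes. Beside a count of 0, the limit of 3 counts of the total is given as well.

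Coordinates are 1-based positions on dm6. Arm lengths and sequence came from the same assembly, and genes came from Ensembl release 115 with FlyBase symbols, without transposable elements, on the 6 arms 2L, 2R, 3L, 3R, 4 and X. This left 13945 protein-coding genes. The dm3 lists were only counted and compared with each other, since no dm3 annotation was used here and no coordinates were converted. A promoter peak had its summit within 500 bp of an annotated transcription start site (TSS), and all other peaks are called distal.

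Reproducibility was measured on the strongest peaks of each replicate, as many as the thresholded list holds. The share with a summit within 100 bp of a summit in the other replicate was set beside 1000 circular shifts of all summits along each arm. Spearman's and Pearson's correlations of log2 signal were computed across thresholded peaks matched in both replicates. The promoter share was compared with 1000 circular shifts, which keep the spacing of peaks (1-sided permutation test). Median signals of promoter and distal peaks were compared with 100000 permutations across peaks (2-sided).

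For 20 lists of genes, the share of protein-coding genes with a thresholded summit within 1 kb of a TSS was compared with all other protein-coding genes by Fisher's exact test (2-sided), with Benjamini-Hochberg adjustment over the 20 lists. The lists covered the E(spl) complex, Bearded family, Notch and EGFR pathways, proneural, neuroblast, neuronal, glial, segmentation, Hox, mesoderm, muscle and cell cycle genes, with ribosomal protein, housekeeping, chemoreceptor and chorion and yolk genes as lists less tied to Notch signalling. Of the symbols written down, 5 were dropped as absent from the annotation or repeated under another name, and 4 entries were matched through a newer symbol (hry, Delta and Nct). For 14 motifs and 4 control sequences of the same base content as 2 of them, the share of windows reaching 50 bp to each side of the summit with a match on either strand was compared with windows of that width centred 300 bp to a randomly chosen side, by an exact McNemar test (2-sided) adjusted over the 18 sequences. The 8 peaks of the E(spl) complex were compared in number with all windows of the same width taken every 10 kb.

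The rule for naming items took the 20 strongest thresholded peaks, each with the protein-coding gene of the nearest TSS. It also took every peak and gene of the E(spl) complex, up to 4 members with the strongest peaks and up to 4 without a peak per gene list, and up to 5 of the strongest peaks missing from each replicate's list. Tests, lists, motifs, this rule and most alternative settings were fixed before the data were examined. Alternatives changed the overlap rule, the distance to the TSS, the assignment of peaks to genes, the motif window and background, the build, and the threshold, and replaced the thresholded list by the strongest peaks of 1 replicate. Peaks and genes are not independent replicates, and neighbouring genes can share a peak, so p-values across them describe these lists and not the spread between embryos.

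The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. The steps named next were tested on simulated data; the E(spl) window counts, motifs by peak strength and the 8-base search were not. The overlap step found 70.0% of 5701 simulated summits where 69.8% had been kept in place. The gene-list step found a peak at 67.0% of the genes of a planted list, the true share, and called 4.00% of 200 random lists at an unadjusted p under 0.05. The motif step recovered CACGTG in 4.09% of windows, as planted. In a first draw with nothing planted, 58 windows held CACGTG against 34 of their shuffled copies (exact McNemar p = 0.016), although the true difference was 0. The test was then repeated on 360 comparisons between shuffled windows, of which 2.78% were called at an unadjusted p under 0.05. The promoter step gave 12.9% for shifted peaks, whose own shifts gave 13.5% (permutation p = 0.83). The signal step gave a ratio of 118.9% for a planted 120%. The correlation step gave 79.5% of a perfect Pearson correlation for a planted 80%, and the step with matched lists called 3.5% of 200 random lists.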

Results

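E(spl)m3-HLH is a basic helix-loop-helix transcriptional repressor of the Hairy/Enhancer of split family, encoded in the E(spl) complex, whose genes are turned on by Notch signalling. The data describe where a GFP-tagged copy of this protein was recovered on the genome of whole embryos of mixed age, 0 to 24 h. They consist of 1 group, the E(spl)m3-GFP ChIP, with 2 biological replicates (replicates 2 and 3) and no untreated or control samples among those analysed. The deposited peak lists on build dm6 held 30000 peaks for replicate 2, 24781 for replicate 3 and 25791 for the pooled alignments. Whether the list of replicate 2 was limited to that round number is not given in the sources used here, and values over whole lists depend on it. The thresholded list held 5701 peaks. Signal is the authors' own value per peak, on a scale of its own in each list, and sequencing depth is unknown. Values for the 2 replicates are therefore given side by side and not averaged.

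The first comparison asked how far the replicates gave the same sites. The strongest sites were nearly the same: of the 500 strongest peaks of replicate 2, 497 (99.4%, 95% interval 98.3 to 99.8) had a summit within 100 bp of one of the 5701 strongest summits of replicate 3, and 498 of 500 did in the other direction. Over all 5701 strongest peaks, 4460 of replicate 2 (78.2%, interval 77.1 to 79.3) were found in replicate 3, and 4462 of replicate 3 (78.3%) in replicate 2. Circular shifts of the summits gave 0.864% on average and at most 1.30%, with a permutation p of 0.001, the smallest that 1000 shifts can give. Of the weakest 1000 of those 5701 peaks, 45.3% of replicate 2 (interval 42.2 to 48.4) and 43.6% of replicate 3 had a partner among the other's 5701 strongest, where a partner ranked just below that cut counts as missing. With partners sought in the whole list of the other replicate, an alternative chosen after seeing the data, these were 84.8% and 89.2%, and 93.2% and 94.8% of all 5701. When every peak of each list was used, 42.4% of the peaks of replicate 2 and 51.4% of those of replicate 3 had a partner.

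Every one of the 5701 thresholded peaks was present unchanged in the pooled list, and together they were exactly its 5701 strongest peaks. A summit within 100 bp was found for 5624 of them (98.6%) in replicate 2 and for 5542 (97.2%) in replicate 3, at a median distance of 6 bp and 14 bp. Across the 5473 peaks matched in both replicates, signal was correlated with Spearman's rho 0.813 and Pearson's r 0.865 on the log2 scale. This is a correlation across peaks of 2 samples, and peaks are not independent replicates. The thresholded list came from the IDR procedure on these same replicates. Its peaks coincide with a cut on signal in their pooled alignments, not with a choice by each peak's own replicate ranks. Part of the agreement in this paragraph therefore follows from that choice.

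**Figure D1:**
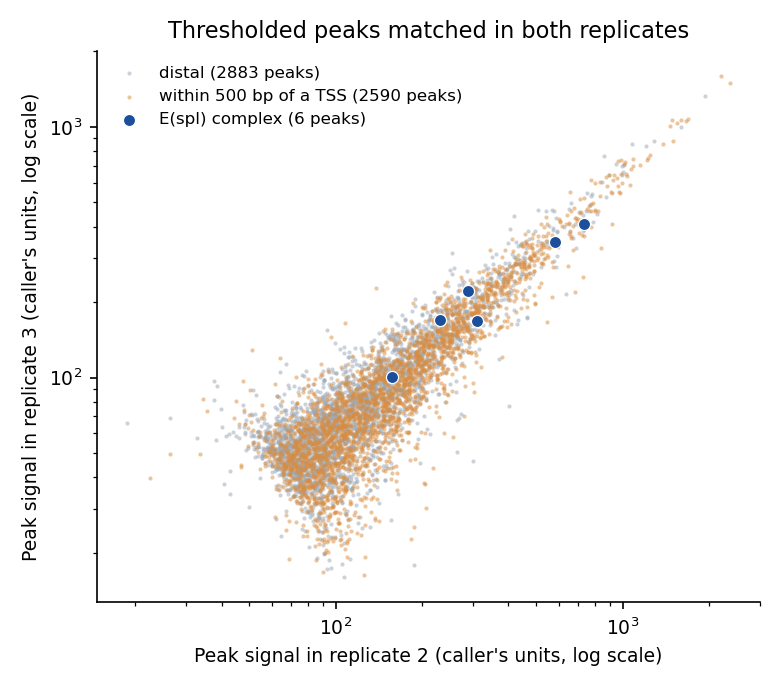
Signal of each thresholded peak in replicate 2 (horizontal) and replicate 3 (vertical), both in the caller's units on log scales, for 5473 peaks matched in both replicates. Points follow 1 diagonal and spread at the weak end, and the 6 matched peaks of the E(spl) complex lie within the cloud.

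Most thresholded peaks without a matching summit in a replicate still overlapped a peak there. Of 77 thresholded peaks with no summit within 100 bp in replicate 2, 72 did so, as did 148 of 159 in replicate 3, and among the 5 strongest of each these were 4 and 5. In replicate 3 the strongest such peaks lay near nrv1, a subunit of the sodium pump (2L 6786946 to 6787405, pooled signal 693), Snx21 (2L 2765621 to 2765971, 612), and Ldh, lactate dehydrogenase (3L 6262692 to 6262911, 544). A peak in an intron of simj followed, at 3L 10678559 to 10678974 (493). In replicate 2 they lay near SH3PX1 (3L 9713820 to 9713995, 310), vir (2R 23366346 to 23366761, 286), ced-6 (2R 9441649 to 9441826, 278) and, in an intron of arr, at 2R 13472307 to 13472722 (253). An intergenic peak 12600 bp from the nearest TSS, that of tal-2A (3R 13800434 to 13800654, 375), had no summit within 100 bp in either replicate.

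Thresholded peaks were spread over all arms. Their median width was 416 bp, with a range of 104 to 809 bp. The whole pooled list had the same median and range, and 3929 of the 5701 summits lay at the middle of their interval. Width is therefore not read here as the extent of a bound site. Density was 44.2 peaks per Mb on 2L, 38.5 on 2R, 43.9 on 3L, 42.5 on 3R and 45.5 on X. Chromosome 4, the small and largely heterochromatic autosome, held 20 peaks or 14.8 per Mb, 0.351 times the density of arms 2L to 3R (exact binomial test by length, p = 3.2e-08). X held 1.08 times that density (exact binomial p = 0.030). The strongest 5701 peaks of each replicate gave 1.06 and 1.04 times for X in replicates 2 and 3, while the complete lists gave 1.05 and 0.926 times.

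The highest signals belonged mostly to promoters of genes of varied function, and no gene nearest to the first 20 peaks was in the gene lists. First came a peak 96 bp upstream of the TSS of CG14100 (3L 19590416 to 19590833), with pooled signal 3847 and ranks 1 and 2 in replicates 2 and 3. The next was 36 bp upstream of Ugalt, a UDP-galactose transporter (X 2703665 to 2704118, signal 3782). The third lay in an intron of ush, 1369 bp upstream of the TSS of cbt (2L 480875 to 481326, signal 3285). Peaks ranked 4 to 9 were at px (2R 22514087 to 22514510, 2757), Art3 (3R 15229314 to 15229753, 2703), Chro, a chromodomain protein (3L 22878688 to 22879120, 2664), CG11050 (2L 6612484 to 6612916, intron, 2588), CenG1A (2L 13835258 to 13835669, 2532) and ph-p, a Polycomb group gene (X 2137147 to 2137570, 2529). The others of the first 20 had CHMP2B, mRpL41, PNPase, Lk6, CG32772, CG1888, CG5611, tara, CG18549, Pal1 and CG7601 as nearest genes, with signals from 2456 down to 1821. Of these 20 peaks, 15 were promoter peaks and 13 had summits within 200 bp of a TSS. In both replicates 17 of them were among the first 20, and the worst rank of any was 27.

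Promoters held 2707 of the 5701 thresholded summits (47.5%, interval 46.2 to 48.8). Circular shifts gave 13.6% on average, a ratio of 3.50 (1-sided permutation p = 0.001, the smallest that 1000 shifts can give). Introns held a further 2010 summits (35.3%, against 39.5% in shifts), and 843 (14.8%) were intergenic, against 27.2%. Coding exons held only 12 summits (0.210%), where shifts gave 13.1%, and 3' UTRs held 51 (0.895%, against 5.08%). Pooled-list peaks below the threshold had a promoter share of 25.5%, a comparison chosen after seeing the data. Promoter peaks were also stronger. Their median pooled signal was 211 against 179 for distal peaks, a ratio of 1.18, and the ratio was 1.22 in replicate 2 and 1.11 in replicate 3 (2-sided permutation p = 1e-05 in each, the smallest that 100000 permutations can give).

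The E(spl) complex, which encodes the tagged protein, held 8 thresholded peaks between 3R 25997621 and 26041008. The strongest, rank 87 of 5701, lay 392 bp upstream of the TSS of E(spl)m3-HLH itself (3R 26021112 to 26021673). Its signal was 1129 in the pooled list, 732 in replicate 2 and 410 in replicate 3. A second peak 1339 bp upstream of the same gene, at 3R 26020313 to 26020591 in a non-coding exon, had rank 541 and signal 515. Between E(spl)mbeta-HLH and E(spl)malpha-BFM an intergenic peak at 3R 26008919 to 26009248 had rank 136 and signal 929. Others lay 50 bp upstream of E(spl)mbeta-HLH (3R 26005974 to 26006141, signal 260), 556 bp upstream of E(spl)m2-BFM (3R 26017951 to 26018144, 495) and 354 bp upstream of E(spl)m7-HLH (3R 26036651 to 26036816, 407). The remaining peaks were near Kaz-m1, a protease inhibitor gene of the complex (3R 26014172 to 26014587, 198, and 3R 26012761 to 26013176, 120), and had no summit within 100 bp in replicate 3.

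A summit within 1 kb of a TSS was present for 6 of the 12 protein-coding genes of the complex. These were E(spl)mdelta-HLH, whose peak lies just outside the complex (3R 25997085 to 25997500, signal 271), E(spl)mbeta-HLH, Kaz-m1, E(spl)m2-BFM, E(spl)m3-HLH and E(spl)m7-HLH. None was present for E(spl)mgamma-HLH, E(spl)malpha-BFM, E(spl)m4-BFM, E(spl)m5-HLH, E(spl)m6-BFM and E(spl)m8-HLH, whose nearest summits were 1399 to 6949 bp away. Groucho (gro), the corepressor of this family and the neighbour of the complex, had a peak 132 bp from its TSS (3R 26042347 to 26042663, signal 869, rank 156). With 8 peaks in 43.4 kb the complex was denser than most of the genome: 1.85 would lie in such a length on average, and 322 of 13365 windows of that width (2.41%) held as many. The strongest peaks of replicate 3 alone and of replicate 2 alone each put 10 peaks there, reached by 0.711% and 0.741% of windows, and the stricter list of 2850 peaks put 7 there, reached by 0.486%. The complex also held 25 pooled-list peaks below the threshold, where 6.51 would lie on average.

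**Figure D2:**
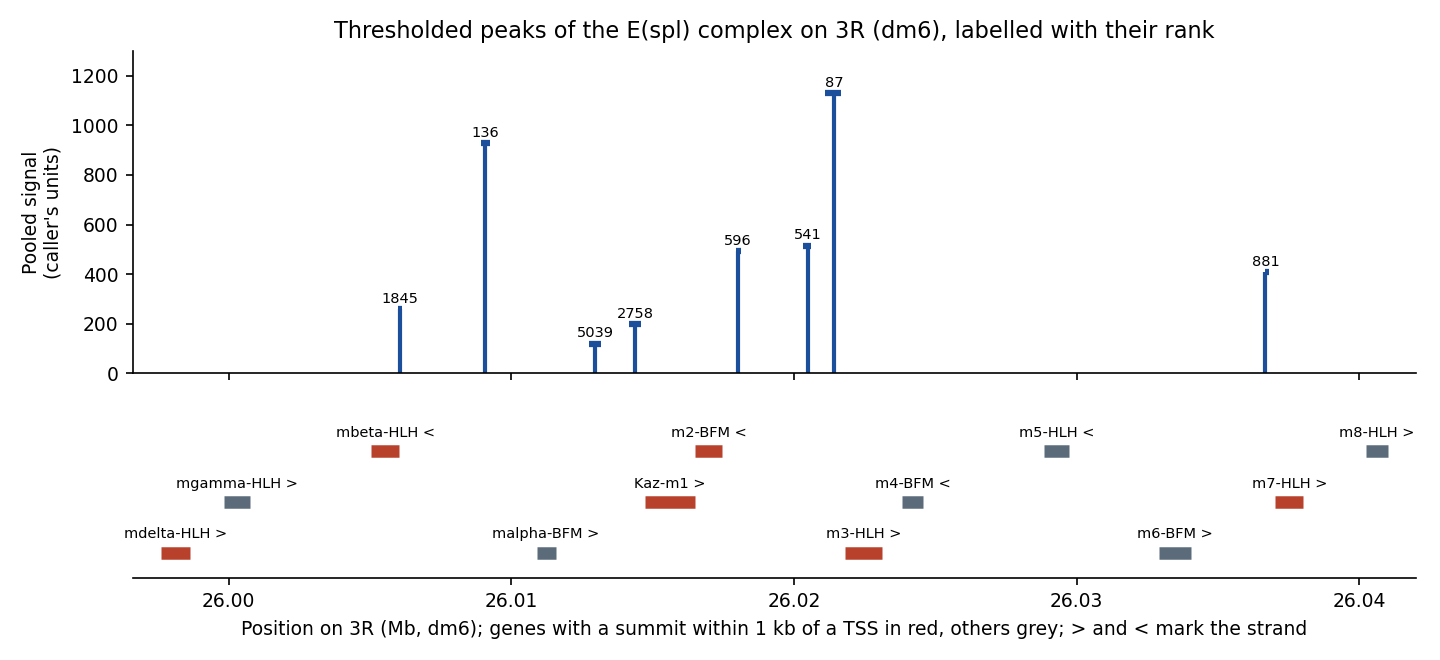
Thresholded peaks of the E(spl) complex by position on 3R (Mb, dm6), with pooled signal in the caller's units above and genes below. Numbers at the peaks are ranks among 5701, genes with a summit within 1 kb of a TSS are red, and the highest bar, rank 87, stands upstream of E(spl)m3-HLH.

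Gene lists asked which kinds of genes carried peaks. Of 13945 protein-coding genes, 3734 (26.8%) had a thresholded summit within 1 kb of a TSS. Of the 20 lists, 2 passed an adjusted p of 0.05, and 3 had an unadjusted p under 0.05. Ribosomal protein genes carried peaks most often, at 62 of 85 (72.9%, interval 62.7 to 81.2; odds ratio 7.48, Fisher's exact adjusted p = 1.5e-17). The odds ratio was 4.91 with the strongest peaks of replicate 3 alone, 4.27 in the stricter list and 3.32 against genes with any pooled-list peak, a background chosen after seeing the data, and all 3 passed the threshold. The strongest were at RpS27 (signal 650), RpL34b (643), RpL7 (638) and RpS20 (537), while RpL10Aa, RpL15, RpL21 and RpL38 were among the 23 without one. Olfactory and gustatory receptor genes, which act in sensory neurons of later stages, carried almost none, at 2 of 119 (1.68%, interval 0.462 to 5.92; odds ratio 0.0462, Fisher's exact adjusted p = 1.0e-12). The odds ratio was 0.0750 in replicate 3 alone, 0.148 within 2 kb (8 of 119) and 0.132 against genes with any pooled-list peak (2 of 18, Fisher's exact adjusted p = 0.014). The genes with a peak within 1 kb were Or88a (signal 522) and Gr32a (185).

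Genes of the Notch pathway and its targets did not pass the test at this distance. Notch pathway components had a peak in 9 of 20 cases (45.0%, interval 25.8 to 65.8; odds ratio 2.24, Fisher's exact adjusted p = 0.252). Beside gro these included numb, an inhibitor of Notch signalling (2L 9449371 to 9449800, 777), aph-1 of the gamma-secretase complex (612), through the same peak as Snx21, and Nle (223). Delta, Ser, Su(H) and H had none. The bHLH genes of the E(spl) complex stood at 4 of 7 (57.1%, interval 25 to 84.2; Fisher's exact adjusted p = 0.252). Bearded family genes stood at 1 of 8, the E(spl)m2-BFM gene, and other Hairy-related genes at 1 of 5, with a weak peak at hry (signal 121) and none at dpn, Hey, cwo or Hesr. Proneural genes and their partners stood at 1 of 10: da, the common partner of proneural proteins, had a peak 85 bp from its TSS (2L 10387812 to 10388227, signal 224), whereas ac, sc, l(1)sc and ase had none. With so few genes per list, the intervals are wide. Those of Notch pathway components and E(spl) bHLH genes start just under the 26.8% of all genes and reach well above it. Those of the Bearded, other Hairy-related and proneural lists reach well to both sides. Random lists matched on numbers of TSSs and neighbouring genes gave 14.3% on average for the E(spl) bHLH genes (permutation p = 0.016, adjusted 0.107). These genes are neighbours in the complex but were drawn as if independent. For Notch pathway components the matched lists gave 34.1% (permutation p = 0.39, adjusted 0.818). They gave 12.3% for the Bearded, 13.4% for the other Hairy-related and 10.6% for the proneural list.

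Neural precursor and neuroblast genes had a peak in 4 of 19 cases, at brat (signal 956), numb, neur (180) and phyl (138), and neuroblast temporal factors in 1 of 7, at grh (176). Differentiated neuron genes stood at 2 of 14, with a strong peak at the pan-neuronal gene elav (X 523296 to 523677, signal 1133, rank 85) and one at Syx1A (232). Glial genes stood at 5 of 9, with moody (X 2050136 to 2050451, 811) and Gs2 (457) highest (odds ratio 3.42), but at 1 of 9 within 500 bp of a TSS (0.413). EGFR pathway genes stood at 5 of 11, with spi, a ligand of the receptor (831), and aos, an inhibitor of the pathway (429), highest. Fisher's exact test passed the threshold for none of these lists, with adjusted p from 0.252 to 0.884.

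No list of patterning genes passed the test within 1 kb of a TSS. Gap and terminal genes stood at 0 of 7, which allows a share of up to 42.9% by 3 counts of the total (upper Wilson limit 35.4%). Pair-rule and segment polarity genes stood at 2 of 15 (ptc and hry), Hox genes at 1 of 8 (Antp, 122), mesoderm and muscle specification genes at 2 of 12 (tin, 351, and htl, 273), and muscle structural genes at 3 of 13 (sls, 467, Tm1 and Act87E). Chorion and yolk genes stood at 0 of 9, which allows up to 33.3% (upper Wilson limit 29.9%). None of these passed Fisher's exact test, with adjusted p from 0.311 to 1. Within 2 kb of a TSS mesoderm genes stood at 6 of 12 (odds ratio 2.08, Fisher's exact adjusted p = 0.341). Cell cycle genes stood at 6 of 11 (CycE, 478, Cdk1, fzr and CycB highest; Fisher's exact adjusted p = 0.252). Highly transcribed housekeeping genes stood at 8 of 13, with Gapdh2 (1106), Act5C (600) and Hsp83 (363) highest (odds ratio 4.38, Fisher's exact p = 0.0088, adjusted p = 0.0588).

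**Figure D3:**
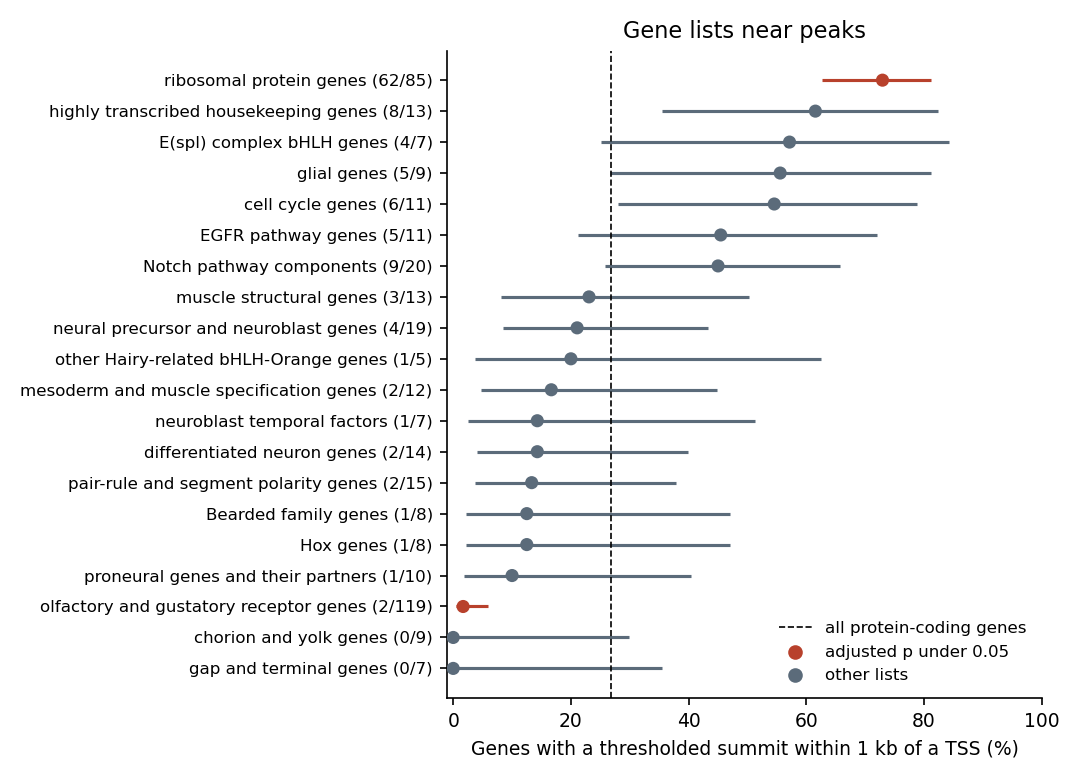
Share of each list's protein-coding genes with a thresholded summit within 1 kb of a TSS (%), with 95% Wilson intervals as lines, counts in brackets and the share of all protein-coding genes, 26.8%, as a dashed line. Red marks adjusted p under 0.05: ribosomal protein genes at 72.9% and olfactory and gustatory receptor genes at 1.68%.

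These calls depended on how peaks were given to genes. With each summit assigned to the gene of its nearest TSS at any distance, 7 lists passed, with neural precursor and neuroblast genes (14 of 19) and EGFR pathway genes (10 of 11) among them. So did pair-rule and segment polarity genes at 10 of 15 (odds ratio 5.72, Fisher's exact adjusted p = 0.0043), Hox genes at 6 of 8 (8.58, Fisher's exact adjusted p = 0.017) and mesoderm genes at 7 of 12 (4.0, Fisher's exact adjusted p = 0.0499), all with odds ratios under 1 within 1 kb. Against random lists matched on the length of a gene's territory, an alternative chosen after seeing the data, pair-rule (66.7% against 42.7%, permutation adjusted p = 0.392), Hox (75% against 50.1%, permutation adjusted p = 0.414) and mesoderm genes (58.3% against 38.2%, permutation adjusted p = 0.4) no longer passed. Neural precursor (permutation adjusted p = 0.02) and EGFR pathway genes (permutation adjusted p = 0.028) still did. With gene bodies and 2 kb around them, 4 lists passed, EGFR pathway genes and mesoderm genes (10 of 12) among them. With the strongest peaks of a single replicate in place of the thresholded list, 4 lists passed in each case, adding housekeeping genes in both (odds ratio 4.70 in replicate 3 alone and 8.83, or 10 of 13, in replicate 2 alone), cell cycle genes in replicate 3 alone (7 of 11) and Notch pathway components in replicate 2 alone (12 of 20). Housekeeping genes also passed with 1 gene per 20 kb (5.38, Fisher's exact adjusted p = 0.022). They did not with the nearest TSS (2.45) or against genes with any pooled-list peak (2.12). Nor did they within 500 bp (3.86) or 2 kb (3.33) of a TSS, with gene bodies and 2 kb (2.37) or in the stricter list (4.47).

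The last comparison asked which recognition sequences lay at the summits. Summits were rich in A and T: windows reaching 50 bp to each side had 33.6% G+C, against 44.4% in windows 300 bp away, and 31.6% at the 500 strongest peaks. Of 18 sequences, 3 were more frequent at the summit. TATCGATA, the DNA replication-related element (DRE) of promoters, was present at 1.67% of summits and 0.649% of flanks (ratio 2.57, exact McNemar adjusted p = 5.2e-07). Its ratio ranged over the other settings with promoter peaks from 1.86 in the stricter list to 7.31 with flanks 600 bp away and 11.9 against shuffled windows, past the threshold in each. GGTCACACT, a core promoter motif, was present at 0.544% and 0.210% (ratio 2.58, exact McNemar adjusted p = 0.0081), and CATATG at 3.89% and 2.81% (ratio 1.39, exact McNemar adjusted p = 0.0023). TATCGATA was at 90 of 2707 promoter summits (3.32%) and 5 of 2994 distal ones (0.167%). With promoter peaks left out, none of the 3 was past the threshold, with ratios of 1 for TATCGATA, 5 for GGTCACACT (0.167% against 0.0334%) and 1.18 for CATATG, which was at 4.34% of distal and 3.40% of promoter summits. In the strongest peaks of replicate 3 alone, GGTCACACT (ratio 1.43) and CATATG (1.21) were not past it. CATATG was also not past it within 25 bp of the summit (1.34), with flanks 600 bp away (1.19) and against shuffled windows (1.24), nor was GGTCACACT in the stricter list (1.4).

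The boxes that proteins of this family are known to bind were not more frequent at summits. CACGTG was present at 39 summits (0.684%, interval 0.501 to 0.934) and 1.70% of flanks (ratio 0.402, exact McNemar adjusted p = 1.2e-06). CACGCG was present at 67 summits (1.18%) and 2.81% of flanks (ratio 0.419, exact McNemar adjusted p = 1.2e-09), and the N-box CACNAG at 9.70% and 11.8% (ratio 0.819, exact McNemar adjusted p = 0.00047). GGCACGTG was at 5 summits and 6 flanks. The control sequences CTGCAG and CCAGCG, of the same base content as CACGTG and CACGCG, were likewise rarer at summits, with ratios of 0.413 and 0.298, while GCATGC (0.750) and GTGCAC (1.23) were not past the threshold. GTGCAC was more frequent at summits and past it within 100 bp (1.85, exact McNemar adjusted p = 1.5e-17), with flanks 600 bp away (1.78), without promoter peaks (1.77), in replicate 3 alone (1.5) and against shuffled windows (2.08). It was not past it in replicate 2 alone (1.23), within 25 bp (1.04) and in the stricter list (0.964). GCATGC was rarer and past it within 100 bp (0.780), with flanks 600 bp away (0.692) and without promoter peaks (0.583). Against a single shuffled copy of each summit window with the same dinucleotides, an alternative chosen after seeing the data, CACGTG (ratio 0.696) and CACGCG (0.779) were not past the threshold. Nor were the N-box (1.11) and the controls CTGCAG (1.26) and CCAGCG (1.35), whose direction turned.

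Among sequences bound by other factors, the GAGA element GAGAGAG (ratio 0.232), the proneural E-box RCAGSTG (0.660), CAGCTG (0.716) and CACATG (0.667) were rarer at summits than in flanks. Against shuffled windows the direction turned and passed the threshold for GAGAGAG (2.16, exact McNemar adjusted p = 0.014), RCAGSTG (1.53, exact McNemar adjusted p = 1.0e-04) and CAGCTG (2.02, exact McNemar adjusted p = 1.0e-08). CACATG (0.896) was not past it. These ratios rest on a single shuffled copy of each window and can vary with the draw. The Su(H) site YGTGRGAA (0.710), the Zelda site CAGGTAG (0.658) and the Grainyhead site AACCGGTT (0.357) were not past the threshold. YGTGRGAA was rarer and past it in the stricter list (0.410) and with flanks 600 bp away (0.662), and CAGGTAG within 100 bp (0.663). Neither CACGTG nor CACGCG passed a test against peak strength. CACGTG was at 10 of the 1140 strongest and 8 of the 1140 weakest thresholded summits (odds ratio 1.25, Fisher's exact p = 0.814; 0.856 with all peaks split at the median and 0.331 without promoter peaks, the latter chosen after seeing the data), and CACGCG at 10 and 19 (odds ratio 0.522, Fisher's exact p = 0.134).

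**Figure D4:**
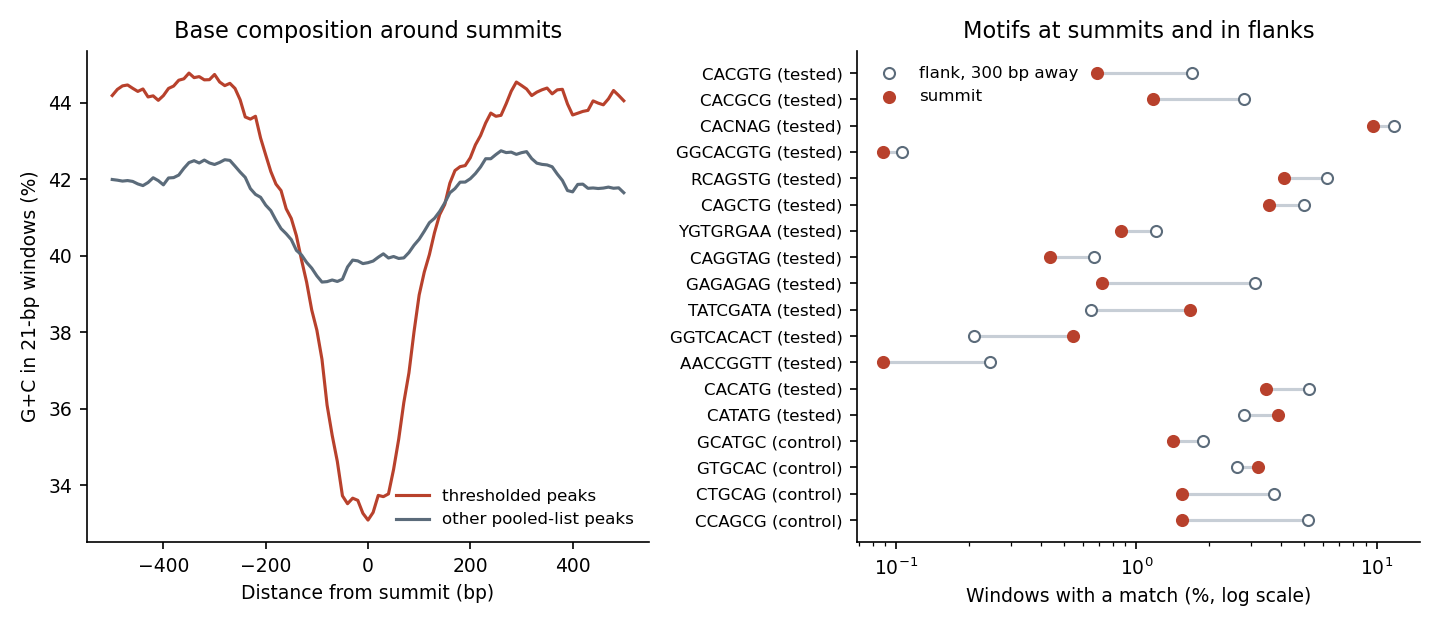
Left, mean G+C content (%) in 21-bp windows by distance from the summit (bp), for thresholded peaks and for pooled-list peaks below the threshold. Right, share of windows with each sequence (%, log scale) at summits (filled) and in flanks 300 bp away (open): G+C content of thresholded peaks is lowest at the summit, and TATCGATA, GGTCACACT, CATATG and the control GTGCAC lie to the right of their flanks.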

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

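A few peaks lay on sequences that none of the comparisons used. On build dm3, 55 peaks of the pooled list, 58 of replicate 2 and 100 of replicate 3 were on heterochromatic or unplaced sequences and not on the 6 arms. There is no control count to set beside these. Most numerous were those on the heterochromatic part of 3L, with 21 in the pooled list, 20 in replicate 2 and 34 in replicate 3. In the thresholded dm3 list, 2 peaks lay on unplaced sequence, with a best rank of 3343 in the pooled list. The dm6 lists used here hold peaks on the arms alone. No control library was analysed, and no explanation of these peaks was tested.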

How the results depend on the processing

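Partners in the whole list of the other replicate, the background of shuffled windows, of other pooled-list peaks, of genes with any pooled-list peak and of lists matched on territory, and peak strength without promoter peaks, were chosen after seeing the data. Of 57 repeats of the answers to a comparison, 39 kept direction and side of the threshold or stayed within their bounds, 16 moved and 2 reversed, and of 323 repeats for single gene lists and motifs, 264 were the same, 18 newly passed, 11 no longer passed and 30 reversed. The promoter share (37.2% to 58.0%), the promoter to distal signal ratio (1.17 to 1.19) and the count in the E(spl) complex (7 to 10) held throughout, while the share of windows with as many peaks ranged from 0.486% to 2.41%. With 1 gene per 20 kb the E(spl) complex bHLH list kept 2 genes, both with a peak, and gave no finite odds ratio. Depth is unknown, and where no construction shows the cause, the cause was not tested.

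Replicate overlap was 83.8% with at least 1 bp shared, 71.1% with 50% reciprocal overlap, 66.1% with summits within 50 bp, 82.5% among the 2850 strongest peaks, 93.2% with partners in the whole list of the other replicate and 42.4% over all peaks (51.4% of those of replicate 3). Spearman's rho was 0.803 with at least 1 bp shared and 0.839 with summits within 50 bp. The stricter list holds 2850 peaks by construction. Lists past the threshold numbered 4 with gene bodies and 2 kb around them, 7 with the nearest TSS, 4 with the nearest TSS against lists matched on territory, and 4 when either replicate was left out. Enriched sequences numbered 1 without promoter peaks and 6 against shuffled windows. For CACGTG and peak strength the odds ratio was 0.856 with all peaks split at the median and 0.331 without promoter peaks.

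Odds ratios crossed 1 for these lists. Within 500 bp it was 0.413 for glial genes, and within 2 kb 2.08 for mesoderm genes. With gene bodies it was 1.65 for neural precursor, 1.11 for neuron, 1.48 for Hox and 7.42 for mesoderm genes. With the nearest TSS it was 1.90 for other Hairy-related, 1.22 for proneural, 8.02 for neural precursor, 5.72 for pair-rule, 8.58 for Hox, 4.0 for mesoderm and 1.27 for muscle structural genes. It was 1.01 for muscle structural genes with 1 gene per 20 kb, 1.04 for mesoderm genes in the stricter list, 0.705 to 1.05 for neural precursor genes without a replicate, and 0.883 for EGFR genes against genes with any pooled-list peak.

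Summit to flank ratios crossed 1 for CAGGTAG at 25 bp (1.08) and without promoter peaks (1.31), TATCGATA without promoter peaks (1), and GGCACGTG (1.33) and GTGCAC (0.964) in the stricter list. Against shuffled windows they did so for CACNAG (1.11), RCAGSTG (1.53), CAGCTG (2.02), YGTGRGAA (1.14), GAGAGAG (2.16), AACCGGTT (1.67), CTGCAG (1.26) and CCAGCG (1.35), of which RCAGSTG, CAGCTG and GAGAGAG passed the threshold as more frequent. Shuffling keeps the low G+C content of the summits and flanks do not.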

Other observations

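The tests on displaced summits, housekeeping genes, extra copies of the E(spl) region, chance picks, a repeated element and weak peaks were chosen only after the results they measure had been seen at least in part, as were those on distal peaks and the genes named there. The other tests of the weighed patterns were set before their results were seen, on patterns already noticed in the same data.

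Peaks far from promoters added neural precursor and EGFR pathway genes when each peak was given to its nearest gene. With each summit given to the nearest TSS, 14 of 19 neural precursor genes had a peak (73.7%), where random lists of genes with as much surrounding sequence had 38.7% on average (permutation p = 0.003, adjusted over 20 lists 0.020). With peaks in the gene body or within 2 kb this list stood at 10 of 19 and did not pass (odds ratio 1.65, Fisher's exact adjusted p = 0.583). For EGFR pathway genes these were 10 of 11 (90.9%) and 44.9% (permutation p = 0.0056, adjusted 0.028). Of the 45 peaks nearest EGFR pathway genes, 34 were more than 1 kb from a TSS, with 10 peaks at pnt, 8 at aop, 7 at S, and 5 each at aos and sty. The highest was 3086 bp from the TSS of aos (3L 16480380 to 16480734, signal 1009, rank 123). Neural precursor genes had 24 peaks, 18 of them beyond 1 kb, for example 1724 bp from the TSS of neur (3R 9031911 to 9032133, signal 468) and 2047 bp from that of insc (2R 20837984 to 20838196, 388). Weak peaks lay near sens (111), esg (144) and SoxN (158).

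Genes for tRNAs, genes of the class annotated as non-coding RNA and pseudogenes carried peaks less often than protein-coding genes. A gene counted if any of its TSSs was near a summit. The classes were not matched on numbers of TSSs or neighbours, so these may cover part of the differences. With 1 gene per 20 kb in each class, 11.7% of tRNA genes and 13.5% of non-coding RNA genes had a summit within 1 kb, against 23.0% of protein-coding genes (odds ratios 0.446 and 0.524, Fisher's exact adjusted p = 0.0047 and 4.9e-15). Pseudogenes had 4.66% (odds ratio 0.164, Fisher's exact adjusted p = 3.6e-11). The test did not pass for snoRNA genes (30.8%, odds ratio 1.49, Fisher's exact adjusted p = 0.114) or snRNA genes (14.3%, Fisher's exact adjusted p = 0.531). Only 3 rRNA genes were left, none with a peak (Fisher's exact adjusted p = 1).

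The scarcity of CACGTG and CACGCG at summits may follow in part from base composition. Either box was in 105 summit windows and in 265 flanks. Shuffled copies of the summit windows held 134.6 on average (central 95% from 113 to 152.5), nearer the number at summits than that in flanks. The summits still held 0.780 times the shuffled number and fell below its range. Flanks were not shuffled, so how much of the gap composition covers is not known. Whether the summits are displaced from the bound sequence was not decided. The highest 50-bp bin within 200 bp of the summit held 0.887 times the level 300 to 500 bp away. That count was not corrected for the lower G+C content near the summit, so a displaced site could stay hidden in it. No biological explanation of the scarcity was tested, and recovery of the tagged protein through other DNA-bound proteins stays open and untested.

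Ribosomal protein genes carried peaks at 2.01 times the share of random genes with as many TSSs and neighbours. They stood at 72.9%, where the matched lists gave 36.3% on average and their central 95% ended at 45.9%. The permutation p was 0.0002, the smallest that 10000 lists can give. All other protein-coding genes stood at 26.5%, so TSSs and neighbours can cover part of the excess but not all of it. Signal at every densely transcribed gene would raise the share of tRNA genes too, but their odds ratio was 0.446. This does not decide the question: tRNA genes were not matched on TSSs and neighbours, and reads from repeated tRNA genes can be lost in alignment. A general signal at genes highly transcribed into mRNA stays open: the other housekeeping genes had an odds ratio of 4.38 (95% interval 1.26 to 17.0, Fisher's exact p = 0.0088), but only 1.30 times the share of lists matched as above (61.5% and 47.2%, permutation p = 0.41, adjusted 0.818). With 13 such genes and no control library analysed here, it cannot be told apart from binding at active promoters.

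The number of peaks in the E(spl) complex went as extra copies of this region in the transgenic line would predict. Binding clustered there could give the same counts, so they cannot tell these apart. Its 25 pooled-list peaks below the threshold exceeded those of 97.8% of the 317 other windows with as many thresholded peaks, whose median was 12. The windows of the same width directly before and after the complex held 3 and 4 of these, but the next 2 windows after it held 6 and 5 thresholded peaks, so the raised thresholded count does not end at the complex. Gene density as the whole cause is argued against, since 4.49% of 980 windows with at least 12 protein-coding genes held as many thresholded peaks. That share is just under the limit set beforehand, and the windows overlap. These windows held a median of 3 thresholded peaks, against 1 over all windows, so gene density may cover part of the count. How the tagged gene was inserted is not given in the sources used here, and binding at the complex by the tagged protein, which would also raise its peaks, stays open and untested.

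Short sequences stood out beside the summits. A first search on arms 2L, 2R and X for 8-base sequences over-represented 40 to 120 bp from summits, relative to 300 to 380 bp, gave 5 picks, of which ATTTAAAA and AAATATAT hold A and T alone. On arms 3L and 3R those 5 occurred 945 times near and 204 times far, a ratio of 4.63, and 1.71% of 933 sites shared their surrounding 40 bases with another. After that result had been seen, a rule of at least 4 G or C bases was added and the search repeated. On arms 2L, 2R and X the picks were then CACTGAGA, CACTGTGC, CAGTGTAG, CTGTGTAC and CAGTGCAC, which contains the control sequence GTGCAC. Of these, CACTGAGA, CACTGTGC and CAGTGCAC had been picks of the first search too. On arms 3L and 3R the 5 picks occurred 432 times near and 64 times far, a ratio of 6.75, which argues against chance among many sequences. Those in both searches repeat counts already seen. The new picks CAGTGTAG and CTGTGTAC occurred 48 and 37 times near and 10 and 11 times far. These arms did not enter the ranking, but they are no independent test, since the rule followed a look at them and such sequences had been noticed on all arms. CACTGAGA alone was found 133 and 11 times there (exact binomial adjusted p = 4.6e-27). None of the sites of the 5 picks had the same surrounding 40 bases as another (0%), which argues against identical copies of a repeated element. Copies that differ at any of these bases were not counted, so a diverged element stays open. Over all arms, including those that gave the picks, the sequences were at 20.5% of distal peaks (interval 19.1 to 22.0) and 8.50% of promoter peaks (Fisher's exact p = 2.9e-38). They were at 18.2% of the strongest and 13.4% of the weakest 1140 peaks (Fisher's exact p = 0.0019). No share far from the summit is given for these groups. Both sides of the summit carried one at 58 distal and 13 promoter peaks, where independent sides would give 37.6 and 5.38 (not tested). Weak peaks of the pooled list had them too, at a ratio of 2.67. Whether a protein binds these sequences was not tested.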
